A study of Mus musculus with 378 samples.

How the data were processed

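The series holds Smart-seq2 libraries, a full-length cDNA method for single cells, of T cells from B16F10 tumours of C57BL/6 mice. Samples were grouped by the genotype, the cell type (CD8 or CD4) and the kind of library (single cell or population) given in each title. This gave 8 groups over 378 libraries, 374 of them single cells. Other parts of the titles, such as p2, p3, the animal words and the 4 that follows KO or WT in both cell types, were not interpreted. Each genotype and cell type has an animal word of its own, and p3 stands in the WT CD4 titles only, with p2 in those of the other groups. The labels name no animal, so each genotype and cell type counts as 1 sample, with its cells as parts of that sample and not as replicates.

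Per the labels' protocols, cells were lysed in Buffer TCL with mercaptoethanol, RNA was captured on SPRI beads, cDNA was amplified over 21 cycles and libraries were made with Nextera XT tagmentation. No molecular identifiers are described, so reads are not counts of molecules. Per the submitters' processing notes, Bowtie and RSEM were used with the mm10 genome, with no versions given. The gene annotation is not given in the sources used here. The values are FPKM as deposited, scaled by the authors across libraries with TMM factors, per the labels' description of the file. FPKM divides estimated fragments by transcript length and library size, so depth is hidden. RSEM shares reads between similar transcripts, so values above 0 can arise for a gene that is not transcribed when it holds repeated sequence, and close paralogs such as Gzmc, Gzmd, Gzme and Gzmf are uncertain. The table holds 23420 genes and 0 of its columns were left unmapped. Mitochondrial genes and T cell receptor constant genes were not analysed here.

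Depth was estimated from the table itself. Low FPKM values of a gene lie on steps of 1 read, and the size of a step across libraries gives their relative depth. Transcript lengths came from GENCODE M21 for 19347 genes. In the kept single cells a median of 80.8% of low values lay within 0.1 of a whole number of reads (74.8% over all libraries). These are estimates and were used for description and for thinning only, with no count test. The estimator was tested on simulated data of 150 libraries with known depth over 23420 genes. The median ratio of estimated to true reads was 0.999, and 88.7% of libraries came within 25%. The simulation used whole reads and the estimator's own transcript lengths, so it does not test errors from wrong lengths or shared reads. No depth is printed for the population libraries, where most genes lie far above the steps.

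Single-cell libraries with at least 1000 genes above 0 FPKM were kept, 298 of 374. No doublet caller was run because cells were processed in separate wells. Among kept cells, Cd4 was found with Cd8a in 3 of 67 WT CD8, 1 of 74 CD8 labelled KO, 3 of 79 WT CD4 and 5 of 78 CD4 labelled KO. With either CD8 chain, Cd8a or Cd8b1, these were 6, 1, 19 and 27 cells. No clustering was done because the titles give the sorted type. For each gene the difference of mean log2(FPKM + 1) over cells, KO minus WT, was computed with a pseudocount of 1. On this scale a difference understates the fold of genes whose values are low. Where many cells are at 0, it can instead far exceed the fold of mean FPKM, since it also follows the share of cells above 0. For Pdcd1 in CD8 cells the difference was -3.92, while mean FPKM was 471 in KO and 1230 in WT. Because there is 1 sample per genotype and cell type, no p-value, standard error or count of changed genes was made. SDs are over cells. Shares of cells above 0 FPKM carry exact Clopper-Pearson 95% intervals, which cover counting error only.

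Before the data were examined, 15 gene lists and 14 lists of cell type markers were fixed. All but 5 of their symbols were matched to a gene, 4 of them under an older name, and those 5 were not analysed here. A list was described by the median of its members' differences, over members above 0 FPKM in at least 10% of the cells of either group. That median was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and its percentile describes these libraries only. Named genes were the 12 with the largest positive and the 12 with the largest negative difference among genes above 0 in at least 20% of the cells of either group. The share of cells and the population libraries also had to differ in the same direction. T cell receptor, immunoglobulin, mitochondrial, predicted, RIKEN, microRNA and small nucleolar genes were left out. Il27ra, Cd4, Cd8a and Cd8b1, the 2 members of each list with the largest difference either way, and, for CD8 minus CD4, the 6 genes either way with the largest value of the smaller of the WT and KO differences were also named. Foxp3, Mki67, Ccr7 and coinhibitory receptors, among others, were fixed for the shares of cells, and further genes outside this rule are given as chosen after their values were seen or as markers of a fixed list. Some genes that these rules name are not reported.

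The differences and list percentiles were tested on simulated data made for the CD8 comparison over 23420 genes, with 200 genes changed by 4-fold. Values of each gene were resampled on their own from WT CD8 cells, which removes correlation between genes. The mean difference was 0.89 where 0.82 was put in for raised genes, and -0.80 where -0.74 was put in for lowered genes. The right sign was found for 91.5% of the changed genes, and 2.50% of 200 unchanged lists fell in the outer 5%. Those lists were random genes, so the simulation does not test percentiles of lists whose genes vary together. Alternatives covered pseudocounts of 0.1 and 10, minimum gene numbers of 500 and 2000, every library, other detection minimums, rescaling, cells with Cd3 genes and the coreceptor of their label, cells matched on genes detected, the log of the mean, and libraries with odd or even numbers. After the data were seen, libraries without B2m or without Cd3 genes were left out in a further alternative, cells holding at least 3 macrophage, class II or dendritic cell markers in another, and estimated reads were thinned to 100000. Coordinates are 1-based, from RefSeq on GRCm38, the assembly called mm10. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.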

Results

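The series compares T cells from B16F10 tumours, a transplanted mouse melanoma, between WT mice and mice labelled as lacking Il27ra, which encodes the receptor chain for the cytokine IL-27. Its stated question is which T cell genes IL-27 induces in the tumour. The titles give 94 WT CD8, 92 Il27ra KO CD8, 94 WT CD4 and 94 Il27ra KO CD4 single-cell libraries, and 1 population library for each. The protocol text names CD8+ T cells only, so CD4 rests on the titles and on the lineage genes. With at least 1000 genes above 0 FPKM, 67 WT CD8, 74 KO CD8, 79 WT CD4 and 78 KO CD4 cells were kept, with medians of 2919, 2797, 2307 and 2650.5 genes. Estimated reads per cell had medians of 311618, 422058, 218276 and 403650, so the WT medians were lower in both types. In WT CD8 cells the quartiles were wider apart (156139 and 674326) than in KO CD8 cells (297344 and 571916). Each group is 1 sample. The values give no error between animals, and no test between genotypes was possible. Il27ra itself was not lower in the single cells labelled Il27ra KO, which bears on every direction given here. Between the CD4 population libraries it was lower in KO.

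Il27ra was above 0 FPKM in 26 of 67 WT CD8 cells (38.8%, interval 27.1 to 51.5%) and 39 of 74 CD8 cells labelled Il27ra KO (52.7%, 40.7 to 64.4%). In CD4 cells it was above 0 in 38 of 79 WT (48.1%, 36.7 to 59.6%) and 41 of 78 labelled KO (52.6%, 40.9 to 64%). Its mean log2(FPKM + 1), ± SD over cells, was 1.57 ± 2.36 in WT CD8 (n = 67), 3.25 ± 3.43 in KO CD8 (n = 74), 3.02 ± 3.41 in WT CD4 (n = 79) and 3.24 ± 3.34 in KO CD4 (n = 78). Above 10 FPKM it was found in 23.9% of WT CD8, 44.6% of KO CD8, 41.8% of WT CD4 and 48.7% of KO CD4 cells. Of the single-cell libraries under 1000 genes, 2.63% had it. In the population libraries Il27ra was 5.60 in WT and 6.52 in KO CD8, and 8.01 in WT and 6.59 in KO CD4, on the log2 scale. There it was higher in KO in CD8 and lower in KO in CD4. The gene lies on chromosome 8 at 84030286 to 84042600. The table gives 1 value for the whole gene, so it cannot tell which exons were read or whether a protein was made.

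The lineage genes followed the CD8 and CD4 titles. Cd8a, a chain of the CD8 coreceptor, was above 0 in 83.6% of WT CD8, 94.6% of KO CD8, 7.59% of WT CD4 and 7.69% of KO CD4 cells. Cd4 was above 0 in 8.96%, 2.70%, 79.7% and 89.7% of the same groups. Cd8b1, the other CD8 chain, was found in 82.1% and 81.1% of CD8 cells and also in 24.1% and 33.3% of CD4 cells. B2m, a gene of nearly all nucleated cells that was looked at after the data were seen, was missing from 8 WT CD8 and 6 WT CD4 cells and from 0 cells of either KO group. The genes Cd3d, Cd3e and Cd3g were all missing from 8 WT CD8, 3 KO CD8, 3 WT CD4 and 1 KO CD4 cells.

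In CD8 cells, the group labelled Il27ra KO had more RNA of naive and memory genes and of immediate early genes. It had less of cell division genes and of some coinhibitory receptor genes. The coinhibitory list was mixed, with 10 of 16 lower in single cells but 11 of 16 higher in the population libraries. Those libraries also held RNA of other cell types. The cell division difference was smaller in cells matched on genes detected. Il7r, the receptor chain for the survival cytokine IL-7, had the largest positive difference of the named genes. Its mean log2(FPKM + 1) was 5.49 ± 3.94 in KO (SD, n = 74) and 1.29 ± 2.73 in WT (n = 67), a difference of 4.20. Pdcd1, which encodes the inhibitory receptor PD-1, had the largest negative one: 2.42 ± 4.34 in KO and 6.34 ± 5.30 in WT, a difference of -3.92. Il27ra was not lower in these KO cells, so the directions follow the label alone.

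**Figure D1:**
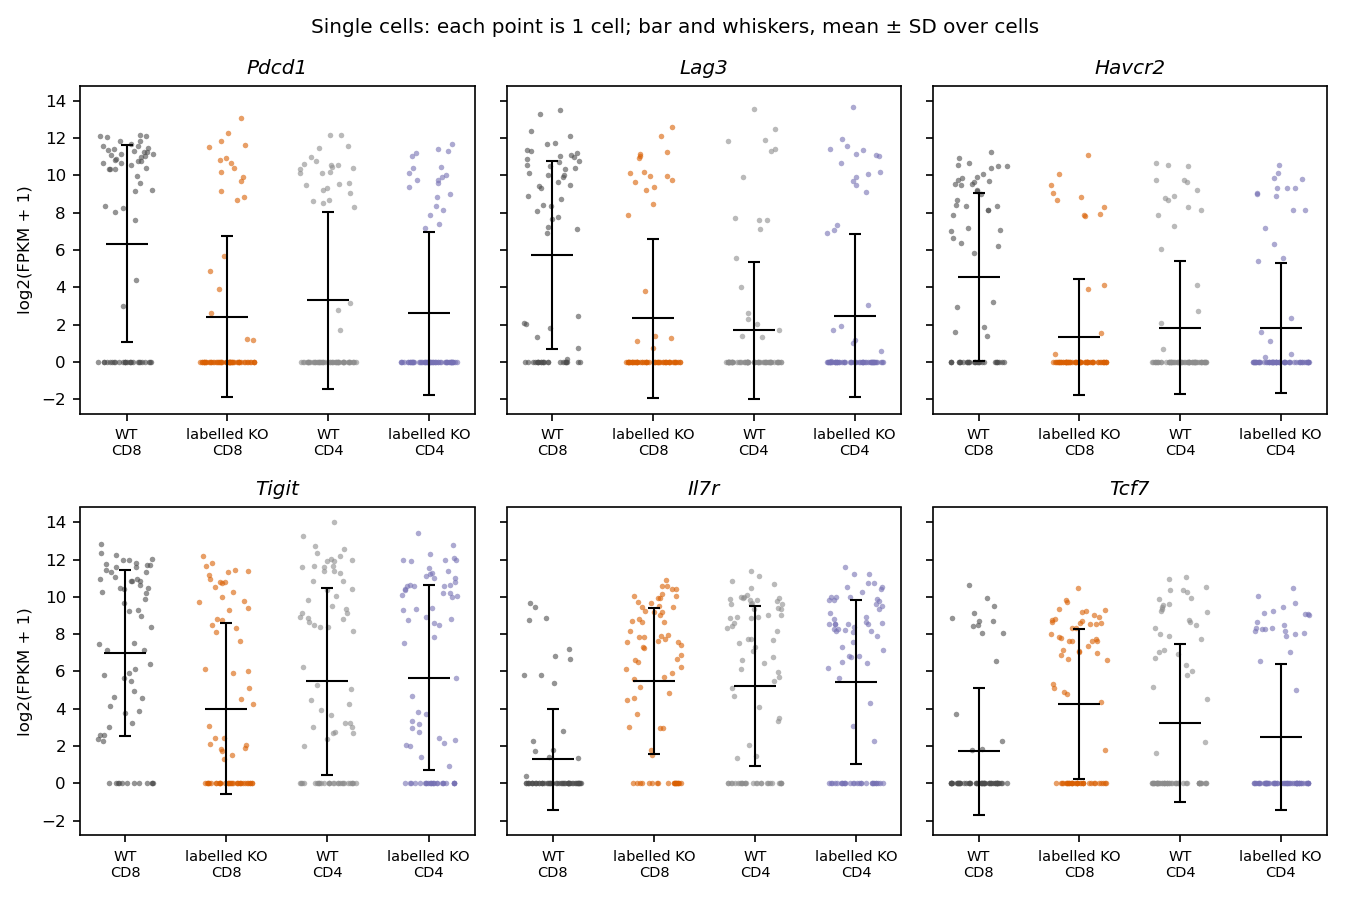
Each point is 1 kept single cell, with log2(FPKM + 1) of Pdcd1, Lag3, Havcr2, Tigit, Il7r or Tcf7 on the vertical axis and the 4 groups on the horizontal axis; lines show the mean and bars the SD over cells. Mean Pdcd1 is 2.42 in KO and 6.34 in WT CD8 cells, and mean Il7r is 5.49 and 1.29.

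After Il7r, the CD8 genes higher in KO were Emb (4.01), Ppp1r15a (3.78), Junb (3.74), Itgb7 (3.62), Nfkbia (3.47), Arid5a (3.24), Rnf7 (3.22), Eif4a2 (3.19), Fos (3.15), Amica1 (2.94) and S1pr1 (2.84). Junb and Fos encode AP-1 factors that are induced within minutes of a stimulus, and Ppp1r15a and Nfkbia are feedback genes of the stress and NF-kB responses. S1pr1, which guides T cells out of tissue, and Itgb7, an integrin chain for gut homing, belong to cell traffic. In the population libraries, whose direction the rule for named genes fixed, these 12 genes differed by 0.11 (Itgb7) to 3.24 (Il7r), with 0.33 for Rnf7, 0.87 for S1pr1 and 1.33 for Nfkbia. Il7r lies on chromosome 15 at 9506159 to 9529941.

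Also lower in KO CD8 cells were Lag3 (-3.40), Havcr2 (-3.21), Gzmk (-3.01), Tigit (-2.99), Rgs16 (-2.66), Entpd1 (-2.60), Hmgn2 (-2.50), Ikzf3 (-2.46), Arsb (-2.46) and Ide (-2.36). Lag3, Havcr2 (TIM-3) and Tigit are inhibitory receptors, and Entpd1 encodes CD39, an enzyme that degrades extracellular ATP. Gzmk is a granzyme of effector memory cells. In the population libraries, again with the direction fixed, the sizes were smaller for the receptors: -0.51 for Pdcd1, -0.25 for Lag3, -0.67 for Havcr2, -0.90 for Tigit and -1.01 for Entpd1. Gzmk was -2.67 there. These sizes are not on the same measure, since a population value is the log of a pooled library and a single-cell value a mean of logs. With the log of the mean over cells, these 5 receptors averaged -1.66 in single cells, against -0.67 in the population libraries. Pdcd1 lies on chromosome 1 at 94038305 to 94052553, Lag3 on chromosome 6 at 124904359 to 124912434 and Havcr2 on chromosome 11 at 46454931 to 46481255.

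Among the gene lists in CD8 cells, proliferation genes were lower in KO for each of 35 members, with a median difference of -1.23, including Stmn1 (-2.15) and Ube2c (-1.99). None of 10000 random lists of like expression was as low, and the population median was -1.31. The population value is limited by melanoma RNA in the WT CD8 population library, where the pigment cell gene Pmel was 12.96, against 3.42 in KO. In cells matched on genes detected the proliferation median was -0.40. Naive and memory genes had a median of 1.70 (12 of 14 higher, percentile 100) and immediate early and stress genes one of 1.38 (13 of 18 higher, percentile 100), with population medians of 1.57 and 1.55. Leaving out libraries without B2m or Cd3 genes brought the immediate early median to 0.69. Exhaustion and activation transcription factors had a median of -0.67 (12 of 17 lower, percentile 0.01), with Tox at -2.34, Irf8 at -1.26 and Nr4a1 at 1.60. The median was -0.36 in cells matched on genes detected and -0.22 with every library. Their population median had the opposite sign, 0.74, and is limited by RNA of other cell types in the population libraries.

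Coinhibitory receptors as a list had a median of -0.48 in CD8 cells (10 of 16 lower, percentile 0.32), and it was -1.07 without libraries lacking B2m or Cd3 genes and -0.83 without cells holding markers of other cell types. The list was mixed: Klrc1 (1.74) and Nt5e (1.56) were higher in KO. Their population median was 1.31, opposite in sign, with 11 of 16 higher in KO. It is limited by RNA of other cell types, as class II antigen presentation genes had population medians of 12.29 in KO and 5.52 in WT CD8. Glycolysis genes had a median of -0.47 (9 of 14 lower, percentile 0.03), with Tpi1 at -2.04 and Eno1 at 1.52, and a population median of -1.26. Cholesterol synthesis genes had a median of -0.55 (13 of 14 lower, percentile 0.40), with Fdps at -1.52 and a population median of -1.21. Melanoma RNA in the WT CD8 population library limits these population medians too. Homing and adhesion genes had one of 0.55 (15 of 20 higher, percentile 98.6) and T helper genes one of 0.49 (5 of 7 higher, percentile 97.6), with population medians of 0.58 and 1.98.

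The other CD8 lists of gene functions lay within the range of 95% of random lists. Genes linked to IL-27 and IL-10 had a median of -0.09 (8 of 16 higher, percentile 29), with Socs3 at 2.04, Il10ra at -2.16 and a population median of 0.38. Interferon-stimulated genes had one of 0.20 (19 of 33 higher, percentile 85.9), with Psmb8 at 1.82 and Gbp7 at -1.64, a population median of 1.01, and -0.44 without libraries lacking B2m or Cd3 genes. Effector and cytotoxic genes had one of -0.06 (11 of 19 lower, percentile 16.4), with Klrk1 at 2.42, Ccl4 at -2.36 and a population median of 0.39, and it was -0.66 without libraries lacking B2m or Cd3 genes. The costimulation list gave -0.08 (9 of 17 lower, percentile 20.6) although Cd69 was 2.73, with a population median of 1.07. The regulatory T cell list gave -0.08 (7 of 13 lower, percentile 49.6), with a population median of 1.08. Housekeeping genes gave 1.18 (13 of 16 higher, percentile 94.7), which became -0.05 without libraries lacking B2m or Cd3 genes, and the population libraries gave 0.02. The median over all detected genes was -0.08.

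Markers of other cell types differed with the CD8 label as well. Class II antigen presentation genes had a median of 0.93 (3 of 3 higher in KO, percentile 99.9) and macrophage and monocyte genes one of 0.37 (5 of 5 higher, percentile 98.3), both above 95% of random lists, and their population medians were 7.12 and 2.40. NK cell genes had 0.56 (1 of 2 higher, percentile 96.8), dendritic cell genes 0.12 (1 of 2 higher, percentile 75), T cell genes 0.33 (7 of 10 higher, percentile 5.13) and the CD8 chains 0.91 (2 of 2 higher, percentile 46). Population medians of these 4 lists were 2.17, 2.86, 0.13 and 0.07. Without cells holding at least 3 macrophage, class II or dendritic cell markers, the CD8 median was 1.94 for naive and memory genes, 1.30 for immediate early genes and -1.24 for proliferation genes. In CD4 cells, T cell genes had a median of 0.52 (7 of 10 higher, percentile 12.7), macrophage genes -0.37 (2 of 2 lower, percentile 3.68) and melanoma genes -0.25 (2 of 2 lower, percentile 5.84). Their CD4 population medians were -0.05, -2.11 and -2.83. The other marker lists had fewer than 2 members detected in 10% of cells.

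**Figure D2:**
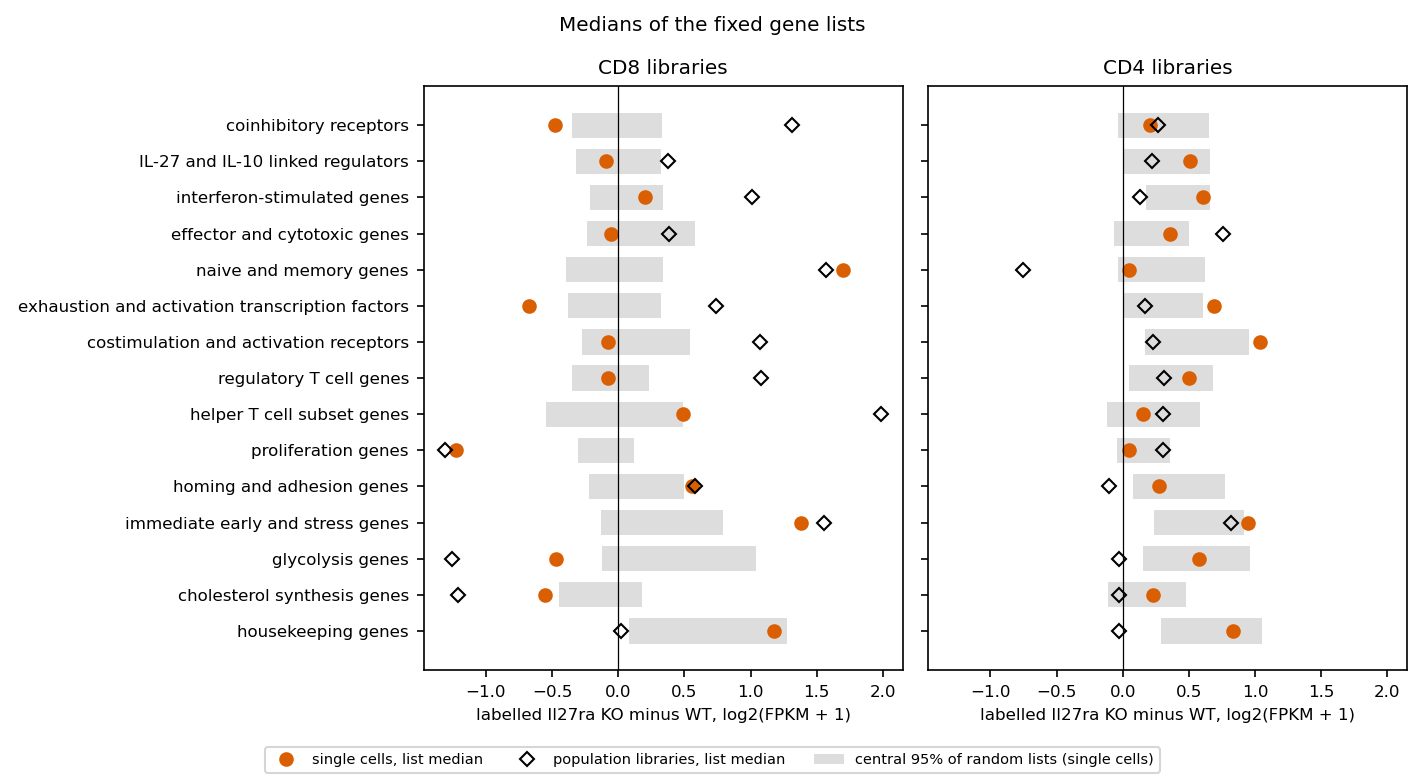
Median KO minus WT difference of log2(FPKM + 1) for each gene list in CD8 and CD4 cells, with the range of random lists of like expression and the population libraries beside it. In CD8 cells the proliferation median is -1.23 and the naive and memory median 1.70; in CD4 cells they are 0.05 and 0.05.

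In CD4 cells, the group labelled Il27ra KO had more RNA of immediate early genes and of costimulation and activation receptors, and less of Cxcr3 and Txnip. Ier2, an immediate early gene, had the largest difference: 7.44 ± 4.09 in KO (SD, n = 78) and 3.80 ± 4.17 in WT (n = 79), 3.64 higher. It was above 0 in 80.8% of KO and 48.1% of WT cells, and 2.76 higher in the KO population library. The WT CD4 titles hold p3 where those of the other groups hold p2, so each CD4 difference goes with that title part as well as with the genotype. Ier2 lies on chromosome 8 at 84661331 to 84662852, close to Il27ra, and Zfp868, a zinc finger gene, on the same chromosome at 69610654 to 69625557. Il27ra was not lower in the CD4 single cells labelled KO, though it was lower in the KO CD4 population library.

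Zfp868 was 3.11 higher in KO CD4 cells and found in 64.1% of KO and 13.9% of WT cells, against 0.37 in the population libraries. The other genes higher in KO were Emp3 (2.95), Nfkbia (2.90), Cish (2.84), Nfkbid (2.73), Anp32b (2.67), Sod1 (2.61), Ifrd1 (2.45), Edf1 (2.44), H2afz (2.42) and Rabac1 (2.40). Cish is a STAT5 target that restrains cytokine signals, and Nfkbia and Nfkbid encode inhibitors of NF-kB. Lower in KO were Rasal3 (-2.06), Cxcr3 (-1.72), Txnip (-1.59), Neat1 (-1.49), Zc3h12d (-1.37), Galnt6 (-1.31), Ubxn6 (-1.26), Cdc42se2 (-1.20), Mob4 (-1.19), Cdadc1 (-1.19), Smim7 (-1.15) and Snapin (-1.09). The population differences, with their direction fixed by the rule, were 0.20 (Nfkbid) to 2.76 (Ier2) for the genes higher in KO and -0.08 (Rasal3) to -2.18 (Zc3h12d) for those lower. Cxcr3 is the chemokine receptor that draws T cells to interferon-induced ligands, and the protein of Txnip restrains glucose uptake.

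The CD4 lists lay mostly above 0, as did the median over all detected genes (0.17). Random lists of like expression had medians of 0.56 for the costimulation list and 0.58 for the immediate early list. They had 0.30 for the exhaustion factor list and 0.41 for the interferon-stimulated list. Part of each list median below is thus shared by other genes of like expression. Costimulation and activation receptors had the highest median, 1.04 (14 of 16 higher, percentile 99.1), with Cd69 at 1.90, Tnfrsf4 at 1.51 and Il2ra at 1.38 and a population median of 0.23. It was 0.49 among odd and 1.58 among even library numbers. Immediate early and stress genes had a median of 0.94 (17 of 18 higher, percentile 98.3), with Ier2 at 3.64 and Nfkbia at 2.90 and a population median of 0.82. Exhaustion and activation transcription factors had one of 0.69 (14 of 16 higher, percentile 99.2), with a population median of 0.17. Its largest differences were Nr4a1 at 1.96 and Egr1, which is in both lists, at 1.81, while Ikzf2 was at -0.67. Interferon-stimulated genes had one of 0.60 (32 of 36 higher, percentile 93.7), with Irf1 at 2.12 and Tap1 at 1.57 and a population median of 0.13. That median was -0.10 in odd and 1.27 in even library numbers, so its direction was not the same in both parts of the libraries.

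Genes linked to IL-27 and IL-10 had a median of 0.51 in CD4 cells (14 of 16 higher, percentile 86.4), with Socs1 at 1.83. Regulatory T cell genes had 0.50 (16 of 19 higher, percentile 82.2), which was 0.04 in cells matched on genes detected. Coinhibitory receptors had 0.21 (8 of 13 higher, percentile 31.9), with Lag3 at 0.79 and Pdcd1 at -0.70. Their median was -0.40 in matched cells and -0.47 in odd library numbers. Effector genes had 0.36 (10 of 15 higher, percentile 84.4), with Lamp1 at 1.82 and Gzmb at 1.52. Naive and memory genes had 0.05 (7 of 14 higher, percentile 7.89), with Tcf7 and Lef1 both at -0.76, while their population median was -0.75 (12 of 14 lower, percentile 0.03). T helper genes had 0.16 (percentile 45.4), proliferation genes 0.05 (12 of 22 higher, percentile 16.5), homing genes 0.28 (percentile 23), cholesterol synthesis genes 0.23 (percentile 64) and housekeeping genes 0.84 (percentile 76.7). Glycolysis genes had 0.57 (12 of 15 higher, percentile 51.4), and -0.03 in odd library numbers. The other population medians were 0.22 for the IL-27 and IL-10 linked, 0.31 for the regulatory, 0.27 for the coinhibitory, 0.76 for the effector, 0.30 for the T helper and 0.31 for the proliferation genes. They were -0.10 for homing and -0.03 for cholesterol synthesis, housekeeping and glycolysis genes.

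The population libraries held RNA of cells other than T cells, which limits them as a second reading of the sorted cells. Melanoma genes had a median log2(FPKM + 1) of 10.19 in the WT CD8 population library, where Pmel, a pigment cell gene, was 12.96, and 0.82 in the KO CD8 one. The class II antigen presentation genes had medians of 5.52 in WT CD8, 12.29 in KO CD8, 10.94 in WT CD4 and 10.57 in KO CD4. The granzyme genes Gzmc, Gzmd, Gzme and Gzmf, chosen after their values were seen, were 11.12, 11.03, 10.05 and 11.86 in the KO CD8 population library but above 0 in at most 4 of 74 single cells. These close paralogs share reads. Across genes, the KO minus WT differences of single cells and population libraries correlated at r = 0.23 in CD8 (9031 genes, 55.7% of the same sign) and 0.16 in CD4 (8176 genes, 52.3%). Genes are not independent replicates.

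The KO minus WT differences of CD8 and CD4 cells correlated weakly across genes. Nfkbia was higher in KO in both types, by 3.47 and 2.90, and Nr4a1 by 1.60 and 1.96. Lag3 was -3.40 in CD8 and 0.79 in CD4, and Anp32b -1.23 and 2.67. Over 7843 genes, Pearson's r was 0.22 and Spearman's rho 0.16, with 52.6% of the same sign. The correlation was 0.02 among cells with Cd3 genes and the coreceptor of their label, and 0.07 among cells with at least 2000 genes. Within 1 type, single cells and population libraries correlated at only 0.23 in CD8 and 0.16 in CD4. A weak correlation between the types therefore cannot show that their differences are unlike.

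For CD8 minus CD4, 6 genes either way were picked by the smaller of their differences in WT and KO, so that both had to be large with the same sign. Higher in CD8 were Cd8b1 (7.28 in WT, 6.88 in KO), Cd8a (6.87, 8.29), the chemokine gene Ccl5 (7.17, 6.63), the cytotoxic granule gene Nkg7 (6.14, 7.24), Ly6c2 (5.84, 6.38) and Ctsw (4.43, 6.67). Higher in CD4 were Cd4 (-6.12, -7.03), the regulatory T cell factor Foxp3 (-3.66, -4.25), the costimulatory receptors Tnfrsf4 (-3.20, -4.78) and Icos (-2.98, -2.98), the interferon-induced GTPase gene Igtp (-2.84, -3.64) and Capg (-3.72, -2.59). Across 9364 genes the correlation of the differences in WT and KO was 0.42, with 60.3% of the same sign.

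The shares of cells above 0 FPKM give the size of these differences in cells. For named genes the rule fixed that the share and the mean went the same way. The genes Tcf7, Top2a, Gzmb and Cxcl10 and the receptor combinations were chosen after their values were seen. Pdcd1 was above 0 in 28.4% of KO CD8 cells (interval 18.5 to 40.1%) and 61.2% of WT CD8 cells (48.5 to 72.9%). Lag3 was above 0 in 28.4% and 65.7%, Havcr2 in 18.9% and 56.7%, Tigit in 54.1% and 82.1% and Entpd1 in 16.2% and 52.2% of KO and WT CD8 cells, while Ctla4 was alike at 54.1% and 55.2%. Pdcd1, Lag3 and Havcr2 were found together in 10.8% of KO and 47.8% of WT CD8 cells. Il7r was above 0 in 73% of KO and 25.4% of WT CD8 cells, Tcf7 in 55.4% and 23.9% and Ccr7 in 32.4% and 5.97%. Tcf7 and Ccr7 mark naive and memory cells.

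Mki67, a gene of dividing cells, was above 0 in 16.2% of KO CD8 cells (8.67 to 26.6%) and 38.8% of WT CD8 cells (27.1 to 51.5%), against 10.3% and 12.7% of KO and WT CD4 cells. Matched on genes detected, the CD8 difference in Mki67 was -6.38 percentage points. Top2a gave 10.8% and 40.3% in KO and WT CD8. Gzmb was above 0 in 33.8% of KO and 56.7% of WT CD8 cells, and in 42.3% of KO and 27.8% of WT CD4 cells. Foxp3 was above 0 in 50% of KO CD4 cells (38.5 to 61.5%) and 38% of WT CD4 cells (27.3 to 49.6%), and the intervals overlap. Odd library numbers gave no Foxp3 difference, with 50% in each group. In CD8 cells, which should lack it, Foxp3 was found in 4.05% of KO and 0 of 67 WT cells. Cxcl10, an interferon-induced chemokine, was above 0 in 24.4% of KO and 1.27% of WT CD4 cells.

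**Figure D3:**
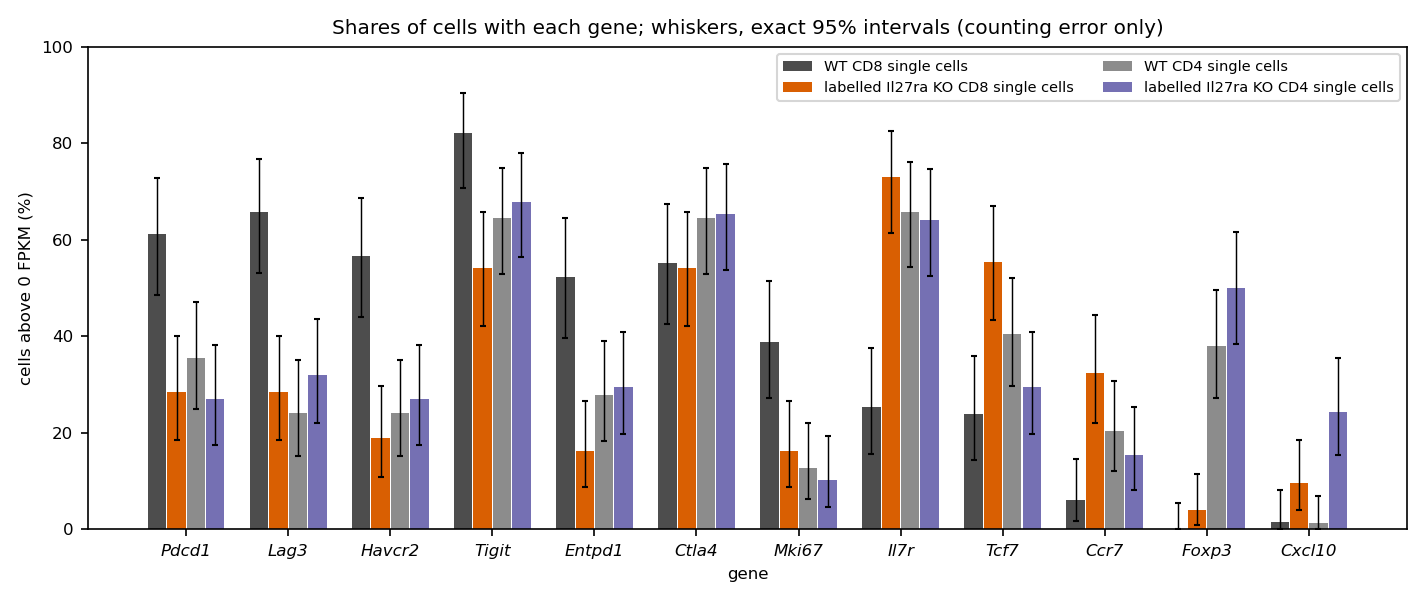
Share of kept cells above 0 FPKM for each gene in the 4 groups, in percent, with exact 95% intervals for counting error. In CD8 cells Pdcd1 is at 28.4% in KO and 61.2% in WT and Il7r at 73% and 25.4%; Foxp3 is largely in CD4 cells.

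In WT CD8 cells the coinhibitory receptor pairs among Pdcd1, Lag3, Havcr2 and Tigit had Spearman's rho of 0.625 to 0.788 over cells, in KO CD8 cells 0.431 to 0.593, in WT CD4 cells 0.367 to 0.624 and in KO CD4 cells 0.040 to 0.486. Over the whole list the median rho was 0.164 in WT CD8, at percentile 47.5 of 1000 random lists of like expression, and 0.024 in KO CD8, at percentile 27.4. The random lists themselves had medians of 0.167 in WT CD8 and 0.038 in KO CD8, so the lower value in KO is not shown to belong to the receptors. In CD4 cells it was 0.203 in WT (percentile 100) and 0.118 in KO (percentile 98.2), with random medians of 0.064 and 0.062. With detection in 25% of cells the WT CD8 median was 0.280, at percentile 85.7. The pairs were not set against random genes.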

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

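The handling and sorting tests, the test without libraries lacking B2m or Cd3 genes for the 5 receptors, and the test of the region around Il27ra were chosen after the results were seen. The other tests of these patterns had their outcomes written first. Even so, the leaving out of libraries without B2m or Cd3 genes, used for the immediate early genes, was itself chosen after the data were seen.

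KO minus WT had opposite signs in CD8 and CD4 cells, in single cells and in population libraries, for 5 named genes and the median of the proliferation genes. Named genes were counted only if the single-cell difference was at least 0.5 in size in both types. They also had to be above 0 in at least 20% of the cells of either genotype in both types. The rule for named genes fixed the population direction in the type that named them. The difference between the types was not tested, since each group is 1 sample. Proliferation genes had a median of -1.23 in 35 members in CD8 cells (population -1.31), -0.40 in matched cells, and of 0.05 in 22 members in CD4 cells (0.31). Melanoma RNA in the WT CD8 population library limits the -1.31. The CD4 median was near 0, at percentile 16.5, and CD8 less CD4 was -1.28. The inhibitory receptor gene Lag3 was -3.40 in CD8 (-0.25) and 0.79 in CD4 (0.19), a gap of -4.19. Anp32b, a chromatin chaperone gene, was -1.23 (-0.71) and 2.67 (0.80), a gap of -3.90, and Emp3, a membrane protein gene, -0.79 (-0.54) and 2.95 (0.53), a gap of -3.74. Cxcr3 was 0.52 (0.45) and -1.72 (-0.22), a gap of 2.24, and Txnip 0.75 (0.87) and -1.59 (-1.18), a gap of 2.34.

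Pdcd1, Lag3, Havcr2, Tigit and Entpd1 were lower in CD8 cells labelled Il27ra KO, by a mean of -3.22 over the 5 genes. These are the coinhibitory list members that were named for a large negative difference in the same cells. Their mean is therefore favoured by the choice, in matched cells too. Over the 16 list members tested the mean was -0.90 and the median -0.48, with 10 lower and 6 higher in KO. In cells matched on genes detected the mean of these 5 genes was -3.02. The matched cells are part of the cells in which the genes were picked, so this value does not decide whether genes detected are a cause. The mean was smaller with other settings: -1.66 with the log of the mean, -2.10 with a pseudocount of 10 and -2.15 with every library. Leaving out libraries that lack B2m or Cd3 genes took WT CD8 cells from 67 to 56 and KO CD8 cells from 74 to 71. Those left out are mostly WT and lower the WT means, which tilts this alternative to a wider gap, so its -4.15 decides nothing. Animal, sort and processing cannot be told apart from genotype with 1 sample per group (population libraries -0.67, for genes named with that direction). A loss of IL-27 signals may also lower these receptors and was not tested. Il27ra RNA was not lower in the KO CD8 cells, and a value for the whole gene cannot tell whether a protein was made.

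Immediate early and stress genes were higher in the cells labelled Il27ra KO of both types. Libraries lacking B2m or Cd3 genes did not account for the whole of it: without them the median was 0.69 in CD8 (percentile 100 of 1000 random lists) and 0.73 in CD4 (percentile 99.9). In cells matched on genes detected it was 1.48 in CD8 (percentile 100) and 1.02 in CD4 (percentile 100). Longer handling of the tumours labelled KO may induce these genes, and the population libraries, at 1.55 in CD8 and 0.82 in CD4, cannot separate it from genotype or, in CD4, from the p2 and p3 of the titles. A response to genotype stays open and untested.

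Some genes differed by over 1 the same way in both cell types, and those near Il27ra may differ because DNA around a targeted gene often comes from another strain. Within 20 Mb of Il27ra, 4 genes did so (2.56%, interval 0.703 to 6.43%), against 2.15% of 7174 genes elsewhere. The 4 genes, Fkbp8, Zfp868, Calr and Ier2, are too few to decide. The source of the targeted allele is not given in the sources used here, so this explanation stays open.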

How the results depend on the processing

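The leaving out of libraries without B2m or Cd3 genes, or of cells with markers of other cell types, and the thinning to 100000 reads were chosen after the data were seen; the other alternatives were planned. Of 450 recomputed list medians, 50 changed sign, 3 of them from a median of at least 0.5 in size. A further limit, a move of more than 1.5 times, or of 0.5 for smaller medians, was passed by 85. Of 624 recomputed differences of named genes, 87 moved, most with a pseudocount of 10 or the log of the mean, and 0 changed sign. Of 120 shares, 11 moved outside their intervals, and of 45 correlations and co-expression values, 41 stayed within 0.1. Leaving out cells with markers of other cell types passed none of these limits, though the small medians of CD8 costimulation (0.22) and CD4 naive and memory genes (-0.13) changed sign. Rank correlations do not depend on the pseudocount, and the detection filter does not change a named gene's difference, so neither was recomputed. No paired analysis was possible because the labels do not say which cells share an animal.

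Unless a cause follows from the alternative's construction, the cause was not tested. A pseudocount of 10, which shrinks differences of low genes, gave CD8 medians of 1.01 for naive and memory, -0.76 for proliferation, -0.36 for exhaustion factor and 0.80 for immediate early genes, and CD4 medians of 0.39 for interferon-stimulated and 0.26 for regulatory T cell genes. The log of the mean gave 1.08 for naive and -0.36 for exhaustion factor genes in CD8 and 0.54 for costimulation in CD4. At least 500 genes gave -0.40 for CD8 exhaustion factors. At least 2000 genes gave -0.66 for CD8 effector genes and, in CD4, 0.40 for interferon-stimulated, 0.49 for costimulation and 0.23 for regulatory genes. Every library gave -0.79 for CD8 proliferation and -0.22 for exhaustion factors. It gave shares in CD8 of -20.8 points for Pdcd1, -27.3 for Havcr2, -18.2 for Tigit and 40.6 for Il7r. No filter gave CD8 medians of 1.05 for naive and 0.59 for immediate early genes. Detection in 25% of cells gave 2.14 for CD8 immediate early genes and a co-expression rho of 0.280 in WT CD8. Cells with Cd3 genes and the coreceptor of their label gave CD8 medians of -1.0 for coinhibitory, -0.64 for effector and -1.13 for exhaustion factor genes, and CD4 medians of 0.31 for interferon-stimulated, 0.53 for costimulation and 0.22 for regulatory genes.

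Matched cells gave -0.40 for proliferation and -0.36 for exhaustion factors in CD8, -6.38 points for Mki67, and in CD4 -0.40 for coinhibitory, 0.64 for costimulation and 0.040 for regulatory genes. Odd library numbers gave CD4 medians of -0.10 for interferon-stimulated and -0.035 for glycolysis genes, both opposite in sign to the reported value. They also gave -0.47 for coinhibitory, 0.49 for costimulation and 0.15 for regulatory genes and 0 points for Foxp3. Even numbers gave 1.27 for interferon-stimulated, 1.58 for costimulation and 1.49 for immediate early genes, 27.1 points for Foxp3 and 31 for Cxcl10. Without libraries lacking B2m or Cd3 genes, CD8 housekeeping genes changed sign to -0.049. The same alternative gave CD8 medians of -1.07 for coinhibitory, -0.44 for interferon-stimulated, -0.66 for effector and 0.69 for immediate early genes, and CD4 medians of 0.34 for interferon-stimulated, 0.61 for costimulation and 0.31 for regulatory genes. The correlation of CD8 and CD4 differences was 0.017 there, 0.021 with Cd3 genes and coreceptor, and 0.073 with at least 2000 genes. Above 10 FPKM, Tigit gave -32.6 and Il7r 51.3 points. Thinning gave -52.8 points for Havcr2 and left out 15 WT CD8, 1 KO CD8, 10 WT CD4 and 2 KO CD4 libraries as too shallow, so depth limits the WT groups most.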

Other observations

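No explanation was tested here, and the genes and the split of libraries by number, but not the cell type lists, were chosen after their values were seen. The CD8 cells labelled Il27ra KO, in which Il27ra was not lower, had more RNA of the NK-type receptor genes Klrk1 (2.42), Klrd1 (1.99) and Klrc1 (1.74) and of the early activation gene Cd69 (2.73), beside less of Gzmk (-3.01) and the chemokine gene Ccl4 (-2.36). None of Pdcd1, Lag3 and Havcr2 was above 0 in 56.8% of these cells and 26.9% of WT CD8 cells.

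Tyr, a pigment enzyme gene of melanoma cells, was above 0 FPKM in 96.3% of kept cells with a mean log2(FPKM + 1) of 3.24, and in 35 of 76 libraries under 1000 genes (46.1%). Other pigment genes were in far fewer kept cells: Pmel in 7.38%, Dct in 4.36%, Tyrp1 in 3.02% and Mlana in 0.671%. Csf3r, Xcr1 and Cd22, markers of neutrophils, dendritic cells and B cells, were above 0 in 55.7%, 49.3% and 31.2% of kept cells, but above 10 FPKM in 2.01%, 4.70% and 0.671%. The T cell gene Cd3e was above 0 in 88.6% of kept cells and 2.63% of libraries under 1000 genes. Rn45s, a ribosomal RNA gene, was above 0 in each kept cell, with median shares of total FPKM of 3.76% in WT CD8, 4.70% in KO CD8, 2.31% in WT CD4 and 3.25% in KO CD4.

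Foxp3 was above 0 in 22 of 44 WT CD4 cells with odd library numbers (50%) and 8 of 35 with even numbers (22.9%). Xist, which is expressed from the inactive X chromosome, was above 0 in 89.6% of WT CD8, 89.2% of KO CD8, 81% of WT CD4 and 83.3% of KO CD4 cells. The Y-linked gene Ddx3y was above 0 in 1, 0, 1 and 2 cells of these groups.

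At least 3 markers of a cell type were found in few cells outside the T cell list. In the order WT CD8, KO CD8, WT CD4 and KO CD4, at least 3 T cell genes were above 0 in 55, 69, 75 and 76 cells. At least 3 macrophage genes were found in 2, 10, 4 and 4 cells, class II genes in 2, 7, 1 and 5, dendritic cell genes in 1, 5, 0 and 2, NK cell genes in 4, 2, 0 and 1 and melanoma genes in 3, 0, 5 and 1. For B cell, neutrophil, fibroblast, endothelial and erythroid genes it was 0 cells in each group. Of the gamma-delta T cell list only Sox13 was analysed here, and it was above 0 in 0 cells.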
